A study of Actinidia chinensis with 4 samples.

How the data were processed

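Total RNA of kiwifruit, Actinidia chinensis cv. Hongyang, was sequenced from inner and outer pericarp collected 90 days after anthesis. Hongyang is a cultivar with a red centre. The outer pericarp is the fruit flesh under the skin, and the inner pericarp is the seed-bearing flesh around the core. There were 4 libraries, 2 from each tissue, sequenced on an Illumina HiSeq 2000 per the labels' protocols. Tissue and stage were taken from the sample characteristics. The labels number no replicates, so replicates 1 and 2 of each tissue are names in deposit order and pair nothing across tissues. The labels describe 2 parallel samples per tissue and do not say whether they came from separate fruits. P-values therefore measure only the spread between these samples, which may be technical.

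The deposited table holds whole-number read counts per gene model, 1 column per library, per the file headers, with no pooling of libraries. The counts were used as deposited. The aligner, the counting program, the genome build and the gene annotation are not given in the sources used here. DESeq is named in the submitters' processing notes, with no version and no stated role. How the counting treated strand and reads that match several gene copies is not given either, so values of gene models that overlap or have near-identical copies are uncertain. The table also holds a length for each gene model. In 100% of the gene models that length was a multiple of 3, so it is called coding length here. Each identifier carries a 2-digit group field, with 30 values from 00 to 29, and a running number, which was used without its last digit to find neighbours. The file does not pair identifiers with gene names or functions, and no genome or annotation was used here. Lists of pigment, regulator, photosynthesis, cell wall, hormone, seed, skin and stress genes had been fixed before the data were examined and were to be matched by name. None of these lists was tested, and no gene is named by function. Whether the inner samples held seed tissue or the outer samples held skin could therefore not be checked.

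Counts were analysed in R 4.3.3 with edgeR 4.0.16. Gene models were kept by filterByExpr, which left 18415 of 39761. Libraries were scaled with TMM factors, and the tissues were compared with the quasi-likelihood test (glmQLFit and glmQLFTest) with tissue as the only term and all 4 libraries in the fit. P-values were adjusted with the Benjamini-Hochberg method, and a gene model was called at an adjusted p under 0.05. Fold changes are inner over outer pericarp on the log2 scale, and their standard errors were derived from the F statistic. CPM values were computed by edgeR from the TMM-scaled library sizes. In the absence of names, at most 2 identifiers in each direction were to be given. These were the ones with the largest fold change among called gene models whose libraries did not overlap and whose mean was at least 5 CPM in the higher tissue. Ach00g022471.2 falls outside this rule and was singled out after its values were seen. The direction of calls in classes of abundance, length and identifier group was compared with Fisher's exact test, two-sided, adjusted within each family of classes; neighbouring gene models are not independent in that test. Shares have exact (Clopper-Pearson) 95% intervals. Where a tissue had 0 counts, a floor of 3 counts summed over its 2 libraries was used. Intervals and floors cover counting error only.

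Totals ranged from 5668276 to 6626024 counts per library. The test was tried on simulated counts drawn from the means, depths and dispersion trend of this comparison. Changes were planted in 200 of 22106 gene models, all of them at 5 CPM or more. Both tissues were given the same dispersion trend, with no scatter of single gene models around it. The unequal spread of the real pairs and such scatter were therefore not simulated, and the rates may not carry over. The test recovered 80% of the 2-fold and 99% of the 4-fold changes, with 1 false call among 180. DESeq2 1.42.0 recovered 64% and 99%, and limma-voom (limma 3.58.1) 79% and 99%. Alternatives fixed before the data were examined were other scalings (median-of-ratios, upper-quartile, library totals), other low-count filters, DESeq2, limma-voom, stricter thresholds, leaving out the 10 most abundant gene models, and leaving out each library in turn. Added after the data were seen were fits without Ach00g022471.2, fits with the 2 inner pericarp libraries summed as 1 sample, fits that combine these, a fit with each library's trend against coding length removed by lowess, and robust empirical Bayes.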

Results

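The libraries held 5668276 and 6626024 counts for inner pericarp and 6616979 and 6000092 counts for outer pericarp. Of the 39761 gene models, 11334 (28.5%) had no count in any library. Between 24517 and 25637 gene models had at least 1 count in a library, and between 18014 and 18168 had at least 10. The single gene model with the most counts was Ach00g022471.2, which lies in identifier group 00 and has a coding length of 708 bases. It took 12.6% of the counts of inner pericarp replicate 2, 14.2% of outer pericarp replicate 1 and 12.9% of outer pericarp replicate 2, and it had 0 counts in inner pericarp replicate 1. Its counts were 837018, 939209 and 771945 in the libraries where it was present, and 0 counts allows up to 3 in the library where it was not. It was the only gene model with 0 counts in 1 library and at least 100 in each of the others. Without it, the totals were 5668276 and 5789006 for inner pericarp and 5677770 and 5228147 for outer pericarp.

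The libraries of a tissue resembled each other more than those of the other tissue, and the inner pericarp pair was much closer than the outer pericarp pair. Across genes, Pearson's r of log2 CPM (prior count 2) was 0.982 between the inner pericarp libraries, 0.975 between the outer pericarp libraries and 0.938 to 0.942 between tissues. Genes are not independent replicates, so these values describe the libraries only. Leaving out Ach00g022471.2, 1 of 6795 gene models at 20 CPM or more differed by at least 2-fold between the inner pericarp libraries, against 22 of 6817 between the outer pericarp libraries. The variation beyond counting noise, as edgeR's common biological coefficient of variation, was 3.12% for the inner pair and 12.4% for the outer pair. A chi-square of the counts over gene models with at least 10 counts came to 1.38 per degree of freedom in the inner pair (20031 gene models) and 5.98 in the outer pair (20182 gene models). Both pairs differed by more than sampling noise, the inner pair by little, and each library was counted as 1 sample. Between libraries of different tissues the same value was 21.4 to 23.8.

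**Figure D1:**
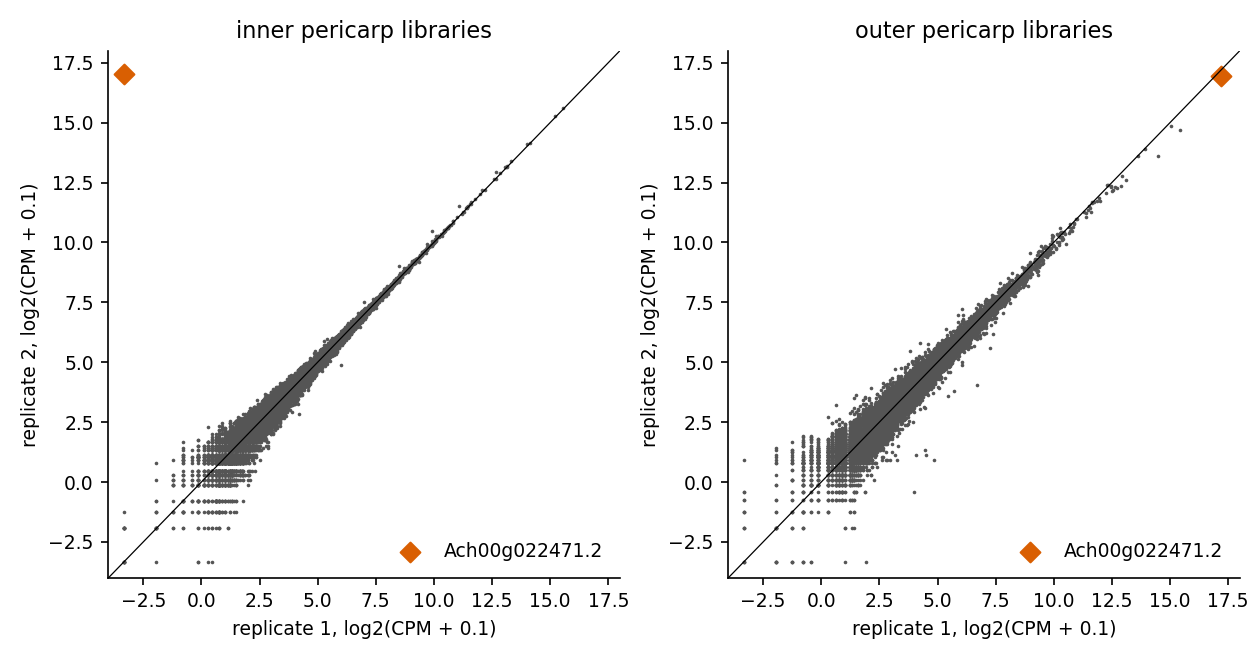
Replicate libraries plotted against each other, inner pericarp on the left and outer pericarp on the right; each point is 1 tested gene model, both axes are log2(CPM + 0.1), and the line marks equality. The inner pericarp points lie closer to the line than the outer ones, and the diamond, Ach00g022471.2, has 0 counts in inner pericarp replicate 1 and 837018 in replicate 2.

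The series compares the inner with the outer pericarp of a fruit whose red pigment is confined to the inner part, in search of regulators of that pigmentation. Of the 18415 gene models tested, 1684 were higher in inner pericarp and 1739 were higher in outer pericarp (edgeR quasi-likelihood test, adjusted p under 0.05), 18.6% of those tested. The called genes were split almost evenly, with 49.2% higher in inner pericarp (exact 95% interval 47.5% to 50.9%). The differences were mostly modest: the median fold was 1.68 among genes higher in inner pericarp and 1.73 among genes higher in outer pericarp. At least a 2-fold difference was seen in 558 and 608 of the called genes, at least 4-fold in 167 and 160, and at least 16-fold in 32 and 27. The libraries of the tissues did not overlap in all 1684 of the inner-higher genes and in 1735 of the outer-higher genes. Over all tested genes they did not overlap in 58.1%. Chance gives 33.3% for 2 against 2 if all 4 libraries vary alike. With the inner pair closer than the outer pair, chance would give more, by an amount not worked out here. The 58.1% and the 33.3% are therefore not directly comparable. The median log2 fold change over all tested genes was 0.00. TMM scaling centres the fold changes, so this median and the even split depend in part on the scaling. The inner-higher share was 48.8% with median-of-ratios factors, 48.4% with upper-quartile factors and 55.2% with library totals. Its exact interval treats genes as independent. The fit with library totals kept Ach00g022471.2. Its 0 counts in inner pericarp replicate 1 lowered that library's total and so raised the scaled values of its other genes. The 55.2% therefore does not show the effect of the scaling alone, and library totals without Ach00g022471.2 were not tried.

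The number of calls changed strongly between fits, both with the libraries used and with Ach00g022471.2 in or out of the fit. A fit without 1 library, or with the inner libraries summed, has 1 sample in a tissue, so all its spread comes from the pair of the other tissue. With Ach00g022471.2 left out, edgeR's common biological coefficient of variation was 12.7% in the fits that rest on the outer pair and 3.11% and 3.13% in those that rest on the inner pair. Without inner pericarp replicate 1 or 2 the test called 888 and 347 genes higher in inner pericarp and 895 and 309 higher in outer pericarp. Without outer pericarp replicate 1 it called 1785 and 1618. Without outer pericarp replicate 2 edgeR called 0 in either direction, although 5301 genes had an unadjusted p under 0.05; with Ach00g022471.2 also left out it called 1628 and 1744. With the 2 near-identical inner pericarp libraries summed as 1 sample it called 0 genes (2781 at an unadjusted p under 0.05), and 736 and 739 when Ach00g022471.2 was left out as well. DESeq2 called 780 and 694 genes. Called genes with at least a 4-fold difference numbered 134 to 213 higher in inner and 152 to 209 higher in outer pericarp over the fits that left out Ach00g022471.2, with or without a library or with the inner libraries summed, and the fit with the length trend removed. The fits with 0 calls had none of these genes.

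**Figure D2:**
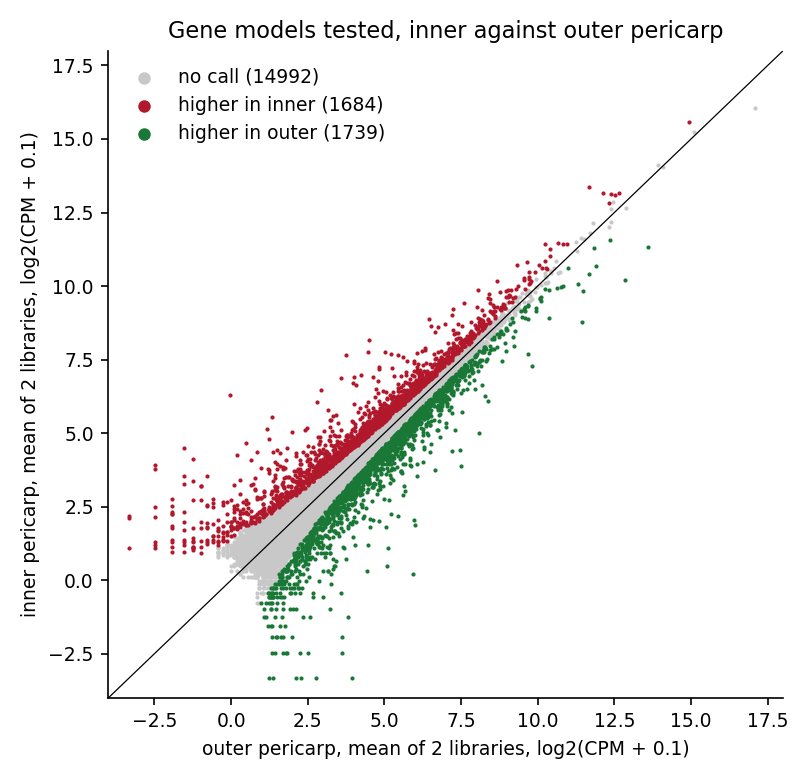
Mean abundance of each tested gene model in outer pericarp (x axis) and inner pericarp (y axis), each the mean of 2 libraries as log2(CPM + 0.1), coloured by the edgeR call; the line marks equality. The 1684 genes higher in inner pericarp and the 1739 higher in outer pericarp flank the line over the whole range of abundance.

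The genes higher in inner pericarp made up a larger part of that tissue's read counts, which were not corrected for gene length. Leaving out Ach00g022471.2, they took 30.0% ± 0.27 (SD, n = 2) of the counts in inner pericarp and 19.3% ± 0.48 (SD, n = 2) in outer pericarp. The genes higher in outer pericarp took 9.69% ± 0.056 (SD, n = 2) of the counts in inner pericarp and 18.6% ± 0.73 (SD, n = 2) in outer pericarp. These sets were chosen on the same libraries, so the shares give the size of the difference and are not independent evidence of it.

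Abundant genes were called more often, and more of those called were higher in inner pericarp. Higher counts give the test more power, and counting noise widens fold changes at low counts. The shares called and the median absolute fold changes are therefore not directly comparable between the classes. Of the 173 gene models at 500 CPM or more, 62 were higher in inner pericarp, 36 were higher in outer pericarp and 75 were not called. Of the 1163 gene models at 100 to 500 CPM, 262 were higher in inner pericarp and 190 in outer pericarp. The inner-higher share of calls was 63.3% (exact 95% interval 52.9% to 72.8%) and 58.0% (53.3% to 62.6%) in these classes, against 45.5% below 5 CPM and 46.5% at 5 to 20 CPM. Fisher's exact test of the direction of calls in a class against all other classes gave an adjusted p of 0.000324 for 100 to 500 CPM and 0.0136 for 500 CPM or more, over 5 classes. The share of genes called rose from 10.7% below 5 CPM to 56.6% at 500 CPM or more; with Ach00g022471.2 and 1 library left out, the latter was 28.5% and 31.4% where the spread came from the outer pair alone, and 77.3% and 81.4% where it came from the inner pair alone. Over all tested genes of a class the median absolute log2 fold change was 0.42 below 5 CPM, 0.23 at 20 to 100 CPM and at 100 to 500 CPM, and 0.37 at 500 CPM or more. Of the 100 most abundant gene models, 34 were higher in inner pericarp, 22 were higher in outer pericarp and 44 were not called, and 14 of the called ones differed by at least 2-fold. With Ach00g022471.2 left out, the numbers higher in inner and in outer pericarp were 21 and 15 without inner pericarp replicate 1, 17 and 15 without inner pericarp replicate 2, 53 and 31 without outer pericarp replicate 1, and 42 and 37 without outer pericarp replicate 2. Among these 100, leaving out Ach00g022471.2, the fitted log2 fold change ranged from -2.67 to 1.69. Without outer pericarp replicate 2 and Ach00g022471.2, the inner-higher share was 53.4% at 100 to 500 CPM (unadjusted p = 0.0196, Fisher's exact test) and 54.9% at 500 CPM or more (unadjusted p = 0.184, Fisher's exact test). Without inner pericarp replicate 2 and Ach00g022471.2 it was 61.2% at 500 CPM or more (unadjusted p = 0.146, Fisher's exact test).

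**Figure D3:**
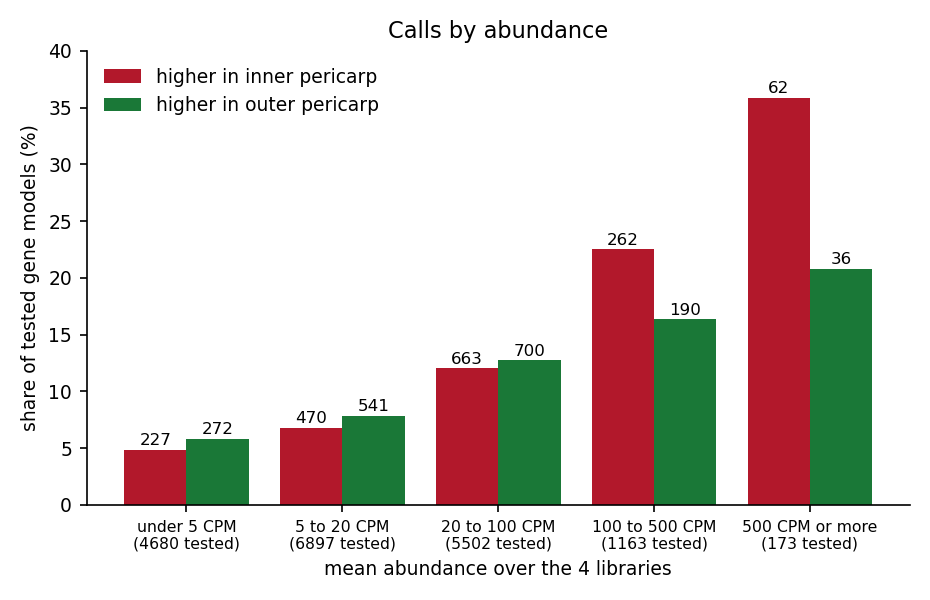
Share of tested gene models called in each direction (y axis, %, with the number of genes above each bar) by mean abundance over the 4 libraries (x axis, CPM). The outer-higher bar is the taller one in the classes below 100 CPM, and the inner-higher bar is the taller one above, with 262 against 190 and 62 against 36 genes.

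The largest differences were in genes of low abundance that were nearly absent from the other tissue. Ach02g037031.2 (identifier group 02, coding length 237 bases) was at 15 ± 1.62 CPM (SD, n = 2) in inner pericarp, with 86 and 100 counts, and had 1 and 0 counts in outer pericarp. Its log2 fold change was 7.22 ± 0.52 (SE; edgeR adjusted p = 3.62e-08), and the ratio of the summed counts was 186-fold with a counting interval of 33.0 to 7380. Its log2 fold change was 6.37 without outer pericarp replicate 2 and 9.54 without replicate 1, the latter a fitted value against 0 counts. Ach03g046121.1 (group 03, 1596 bases) was at 13.6 ± 1.61 CPM (SD, n = 2) in inner pericarp, with 77 and 91 counts against 0 and 1, a ratio of 168-fold (29.7 to 6670; edgeR adjusted p = 6.27e-08). The log2 fold change of Ach03g046121.1 was 6.22 without outer pericarp replicate 1 and 9.39, fitted against 0 counts, without replicate 2. Ach07g240741.2 (group 07, 444 bases) had 0 counts in both inner pericarp libraries and 178 and 11 counts in outer pericarp. In outer pericarp it was 63.0-fold above the floor of 3 counts, with a lower limit of 50.7 from the exact counting interval (edgeR adjusted p = 0.00144). Both values rest mostly on outer pericarp replicate 1, and in the fits without that library Ach07g240741.2 had no test result. Its call was lost in 6 of the 19 alternatives in which it was tested, including DESeq2 (adjusted p = 0.0685) and edgeR with robust empirical Bayes (adjusted p = 0.557). Ach03g434311.2 (group 03, 555 bases) had 0 counts in inner pericarp and 54 and 30 in outer pericarp, 28.0-fold above the floor, with a lower limit of 22.3 from the exact counting interval (edgeR adjusted p = 1.04e-05). With all 4 libraries but no low-count filter, Ach03g434311.2 was not called (edgeR adjusted p = 0.103). Genes with no count at all in the other tissue were few. Only 8 gene models reached 1 CPM in both inner pericarp libraries with 0 counts in outer pericarp, of which 3 were called, and 10 did so in outer pericarp with 0 counts in inner pericarp, of which 6 were called. The rule was applied before the low-count filter, so not being called can mean not being tested. The median of the 8 in inner pericarp was 1.82 CPM, and no gene model with under 25 counts over the 4 libraries was tested. A count of 0 in both libraries of a tissue allows a level of up to 0.24 CPM. The most abundant of these genes was at a mean of 4.44 CPM in inner pericarp and 15.2 CPM (Ach07g240741.2) in outer pericarp, so no abundant gene model met this rule. A count of 1 in the other tissue is enough to fail it, as with Ach02g037031.2 and Ach03g046121.1. Abundant gene models are the least likely to have exactly 0 counts, so the rule cannot show whether any was restricted to a tissue.

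The direction of calls differed with coding length, and in every class but 1000 to 2000 bases it turned with the outer pericarp library used. With all 4 libraries, 56.7% of the called genes under 500 bases of coding length were higher in inner pericarp (195 against 149), as were 55.5% of those of 2000 bases or more (366 against 294), while the share was 43.9% at 1000 to 2000 bases (648 against 828; Fisher's exact test of direction, adjusted p = 2.86e-07 over 4 classes). Without outer pericarp replicate 1 and Ach00g022471.2, the inner-higher share was 74.1% under 500 bases, 60.8% at 500 to 1000 bases and 42.8% at 2000 bases or more. Without outer pericarp replicate 2 and Ach00g022471.2, it was 40.6%, 42.5% and 69.2%. With all libraries it was 50.4% at 500 to 1000 bases. At 1000 to 2000 bases it was 44.9% and 44.2% in these fits, close to the share with all libraries. The outer pericarp libraries themselves differed with length: the median log2 ratio of replicate 1 over replicate 2 was 0.22 for genes under 500 bases and -0.17 for genes of 2000 bases or more, among genes at 5 CPM or more. In the inner pericarp pair the same medians were -0.03 and 0.00. With each library's length trend removed, 1867 and 1912 genes were called, and the inner-higher share was 56.2% (exact 95% interval 51.0% to 61.2%; unadjusted p = 0.00582, Fisher's exact test) under 500 bases, 47.6% (45.1% to 50.1%) at 1000 to 2000 bases and 47.7% at 2000 bases or more. The difference in direction at 1000 to 2000 bases was then no longer significant (unadjusted p = 0.0565, Fisher's exact test). Removing each library's trend also removes any real tissue difference with length. The median log2 fold changes in that fit were 0.004, -0.003, -0.002 and 0 from the shortest to the longest class. The loss of significance therefore cannot tell whether the share of 43.9% came from the libraries or the tissues.

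**Figure D4:**
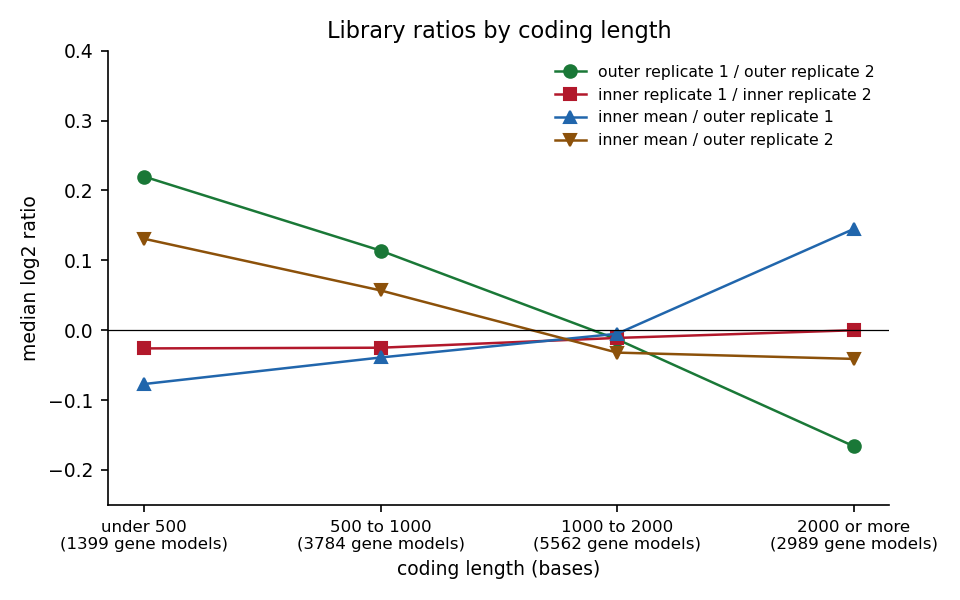
Median log2 ratio between libraries (y axis) for gene models at 5 CPM or more in 4 classes of coding length (x axis, bases). The ratio of the outer pericarp libraries falls from 0.22 to -0.17 with length, the inner pericarp pair stays near 0, and the inner mean moves in opposite directions with length against each outer library.

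No identifier group stood out in its calls after adjustment, which does not show that the spread was even. The inner-higher share of calls ranged from 35% in group 25 to 57.2% in group 03. The share of tested genes called ranged from 15.1% in group 28 to 21.6% in group 12, and in group 00, the largest with 3234 tested gene models, it was 18.5%. In no group did the share called or the direction of the calls differ from the rest by Fisher's exact test after adjustment over 30 groups; the lowest adjusted p was 0.372 for direction, in group 25 (28 genes higher in inner and 52 in outer pericarp), and 0.728 for the share called.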

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

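The fits without Ach00g022471.2, with the inner pericarp libraries summed, with the length trend removed and with robust empirical Bayes were chosen after seeing the data. Values are genes higher in inner and in outer pericarp, 1684 and 1739 as reported. Library totals as the scaling gave 1304 and 1059, with an inner-higher share of 55.2% and a shift of the median log2 fold change of 0.04. That fit kept Ach00g022471.2, whose 0 counts in inner pericarp replicate 1 lowered that library's total. No low-count filter gave 182 and 153 (5565 genes at an unadjusted p under 0.05), with edgeR's prior degrees of freedom at 1.96 against 14.6. DESeq2 gave 780 and 694, of which 777 and 688 were among the reported calls. Requiring at least a 2-fold difference gave 558 and 608, and an adjusted p under 0.01 gave 968 and 901. Leaving out each library in turn gave 0 to 1785 and 0 to 1618; the fit without outer pericarp replicate 2 had 1.8 prior degrees of freedom and 5301 genes at an unadjusted p under 0.05. With Ach00g022471.2 left out too, the counts were 718 and 726 without inner pericarp replicate 1, 635 and 634 without inner pericarp replicate 2, 2120 and 1991 without outer pericarp replicate 1, and 1628 and 1744 without outer pericarp replicate 2. Summing the inner pericarp libraries gave 0 and 0 (2781 genes at an unadjusted p under 0.05; 2.12 prior degrees of freedom), and 736 and 739 (30.3 prior degrees of freedom) with Ach00g022471.2 left out. With 1 sample in a tissue, the spread comes from the other pair: the common biological coefficient of variation was 12.7% in the fits on the outer pair, and 3.11% and 3.13% in those on the inner pair with Ach00g022471.2 left out. Other causes were not tested. The median-of-ratios and upper-quartile scalings, the 1 CPM filter, limma-voom, leaving out the 10 most abundant genes, leaving out Ach00g022471.2 alone (1571 and 1719), removing the length trend and robust empirical Bayes gave 1549 to 1867 and 1627 to 1912. No reported call was called in the opposite direction under any of these alternatives. The 4 named genes kept their direction wherever they were tested; Ach07g240741.2 lost its call in DESeq2 (adjusted p = 0.0685), with no filter (0.337), without inner pericarp replicate 2 (0.0966) and with robust empirical Bayes (0.557). Ach03g434311.2 lost it with no filter (0.103). All 4 lost it without outer pericarp replicate 2 (0.0695 to 0.0994) and with the inner pericarp libraries summed (0.274 to 0.405). The genes counted in 1 tissue only numbered 21 in inner and 29 in outer pericarp at a minimum of 0.5 CPM, and 2 and 4 at 2 CPM. The gene lists were not tested under any setting, because the identifiers were not paired with names. No paired analysis was possible because the labels give no replicate numbers. With 2 libraries a tissue, 2-fold changes were recovered in 80% of simulated cases. All were at 5 CPM or more, with equal spread in both tissues and no scatter around the dispersion trend.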

Other observations

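The tests on Ach00g022471.2, on counting noise and on the length trend as the whole difference were chosen after the values were seen; the others were written down before.

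Genes that follow each other in the numbering of the identifiers tended to change together. Of 7507 pairs of tested gene models with consecutive numbers in the same identifier group, 199 were called in the same direction, 94 of them higher in inner and 105 higher in outer pericarp. In 1000 shuffles of the calls within identifier groups the mean was 128.8 and the highest 170, a ratio of 1.54. The pairs called in opposite directions numbered 119, or 0.919 of the shuffled mean. The ratio was 1.23 at the second neighbour, where the 149 observed pairs lay below the highest shuffle of 155, and 0.997 at the third. There were 16 runs of 3 or more neighbours called in the same direction, the longest of 4 genes. Among pairs with both coding lengths of at least 1000 bases, 76 went the same way against a shuffled mean of 46.0 (highest 72). With the inner pericarp libraries summed as 1 sample and Ach00g022471.2 left out, 58 pairs went the same way against 23.1 expected; that fit takes its spread from the outer pair alone.

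The ratio of 1.54 for consecutive genes argues against a chance order, and the ratio of 0.919 for opposite directions argues against a plain crowding of calls. A single gene annotated as several consecutive models would give pairs at close range, and the ratio of 1.06 at gaps of 5 to 20, with the observed 1405 pairs below the highest shuffle of 1455, leaves that open. Reads shared between near-identical copies were not tested, since the sequences of the gene models were not used here.

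Ach00g022471.2 stood at 0 counts in inner pericarp replicate 1 and at 837018 in inner pericarp replicate 2, the closest pair of libraries in the series. Scaled to the depth of the other genes, replicate 2 predicts 819562 counts in replicate 1, so a lower depth is excluded. Loss of a class of abundant transcripts during library preparation would have lowered other genes as well, but of the 755 other gene models with at least 1000 counts in replicate 2, 0 lay at least 8-fold lower in replicate 1, and their ratios ranged from 0.698 to 1.14. The total of all other genes in replicate 1 was 1.02 times the mean of the other 3 libraries without this gene model, inside their range, which is what a value set to 0 or dropped while the table was made would leave; this remains a hypothesis, because sequencing depth varies freely, and a specific loss of this transcript cannot be ruled out. No biological explanation was tested, since the labels give no difference between these 2 samples.

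The outer pericarp libraries differed more from each other than the inner pericarp libraries. Their chi-square per degree of freedom was 5.98, above the highest of 100 Poisson draws (1.03), so counting noise is excluded as the cause. The libraries shifted with coding length, by 0.324 on the log2 scale between the shortest genes (up to 774 bases) and the longest (1869 bases or more; bootstrap 95% interval 0.309 to 0.339), against -0.025 in the inner pair. This is consistent with different RNA integrity or fragmentation of the outer pericarp libraries, but with the length trend removed the chi-square was still 5.04, so a length trend is not the whole difference. A different mix of inner-like and outer-like tissue stays open. Inner-higher and outer-higher genes lay 0.097 apart (0.07 to 0.119) in the ratio of replicate 1 over replicate 2, against -0.066 (-0.078 to -0.052) in the inner pair. These genes were called on the same libraries, which favours genes whose replicates agree, and the outer ratio also shifted with coding length. The 0.097 is therefore no clean measure of mixing. The bootstrap intervals here resample genes within a pair of libraries as if independent, so they do not cover variation between libraries. Separate fruits for the outer samples and shared material for the inner ones were not tested.

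Among genes with at least 50 counts in either library, 9 were at least 4-fold higher in outer pericarp replicate 1 than in replicate 2 and 4 were at least 4-fold lower, out of 12014, leaving out Ach00g022471.2. In the inner pericarp pair none of 11885 differed that much in either direction.

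The other ways to part the 4 libraries into pairs called 0 genes each with edgeR (59 and 95 at an unadjusted p under 0.05), against 3423 for the tissues. Only 1 of the 3 splits, the real one, reached that number, and 3 splits are too few for a share under 0.05. The other splits put 1 inner and 1 outer pericarp library in each group. The tissue difference then counted as spread within the groups, which holds the calls down. The 0 calls are therefore no baseline for the 3423.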
